A study of Homo sapiens with 10 samples.

How the data were processed

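Total RNA expression was measured in 10 samples of kidney organoid cultures from 1 human induced pluripotent stem cell line, CRL1502 clone C32, which is the same line in every sample. The labels give the same culture protocol for all samples: 8 µM of the WNT activator CHIR99021 for 4 days, then 200 ng/mL FGF9 with 1 µg/mL heparin for 3 days, after which cells were dissociated and pelleted, given 5 µM CHIR99021 for 1 hour, kept in FGF9 for 5 days and then in basal medium for 6 days. Day 7 therefore falls at the end of the flat culture and day 18 at the end of the pellet culture, although the labels do not say at which step the day 7 samples were taken. Batches 4 and 5 are taken as the 2 differentiation experiments of the series description. Replicate numbers run from S1 to S10 without repeats, so they pair no samples.

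The deposited values are counts, 1 column per sample, as raw read counts per gene symbol with the length of each gene model in bases beside them. Per the labels, the authors used STAR 2.4.0h1 and featureCounts 1.4.6 with the genome build hg19. The gene annotation, the strand setting and the treatment of reads with several hits are not given in the sources used here. Reads from overlapping genes and near-identical copies can therefore not be told apart, which leaves the values of HOXC4, HOXC5 and HOXC6 (overlapping transcripts), of the replication-dependent histone genes, of ribosomal protein genes with processed copies and of mitochondrially encoded genes with nuclear copies uncertain in level. The columns were checked to hold whole numbers with a different total in each sample, and no 2 samples of a group had counts as close as 2 readings of 1 library would give (chi-square per gene 2.70 to 10.3 within groups, where 1 is expected from counting alone).

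Total counts were 30.2, 21.3 and 27.8 M for S6, S7 and S8 (day 7, batch 4), 23.0 and 22.1 M for S9 and S10 (day 7, batch 5), 25.5 and 22.7 M for S1 and S2 (day 18, batch 4) and 26.2, 29.9 and 26.2 M for S3, S4 and S5 (day 18, batch 5). At these depths 3 reads correspond to 0.0975 to 0.139 CPM. Structural RNAs held 5.54, 6.19, 5.04 and 5.17% of counts in the 4 groups in the order day 7 batch 4, day 7 batch 5, day 18 batch 4 and day 18 batch 5. RNA28S5, a ribosomal RNA gene, held 1.50% in S10 and 1.01 to 1.09% in the other day 7 samples. Of 42785 genes, 9101 had no read in any sample, and 19410 passed the filter and held 99.9% of reads.

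Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the 4 groups of day and batch, TMM scaling, and a robust quasi-likelihood fit (legacy = FALSE) with 1 coefficient per group over all 10 samples. The plan named the edgeR 4 default; in this version the function itself defaults to the older method, which is among the alternatives. The common biological coefficient of variation was 6.10%. The contrasts were day 18 against day 7 with both batches weighted equally, batch 5 against batch 4 at each day, and the difference between these 2 batch differences (the interaction). Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM are given as mean ± SD on TMM-scaled library sizes. Standard errors can fall below the counting error where few reads were counted, and an SD from 2 samples can do so by chance. A gene whose standard error does so, or which has 3 or fewer reads in a group of day and batch compared, is therefore given as a ratio of pooled CPM with a 95% interval for counting error only, a choice made after the values were seen.

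Before the data were examined, 39 gene lists were fixed from textbook markers, and the 38 with at least 5 measured genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists are over all lists of a contrast. In the file, 752 of 753 list entries were found, for 693 different genes, so some lists share genes and are not independent of each other. Genes named outside the lists follow a rule also fixed before: for the change between days, the 8 genes per direction with the largest change among called genes of at least 10 CPM and 1 direction in both batches; for each batch difference, the 8 per direction with the largest change among called genes of at least 1 CPM on that day; for the interaction, the 5 per direction with the smallest adjusted p. Among called list members, up to 3 per direction with the largest changes come first. From these, members whose call held when each sample was left out were preferred in the text, a choice made after the values were seen.

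Correlations between contrasts are across genes and carry no p. Their chance values came from 100 simulated data sets in which the batches do not differ, so that libraries shared by 2 contrasts count in them. Variance shares are sums of squares of log2 CPM per gene, as medians over genes.

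The procedure was tested on simulated counts with the spread of these data and 200 changed genes of at least 1 CPM per contrast. Changes of 1.5-fold were recovered in 89.6% of genes between the days, 74.6% between the batches at day 7, 76.1% at day 18 and 64.2% in the interaction, and changes of 4-fold in 100%, 98.5%, 97.0% and 93.9%. False calls were 17 of 206, 12 of 181, 12 of 187 and 13 of 165, above the nominal 5% in each.

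Alternatives were RLE scaling or library totals alone, no filter or at least 1 CPM in 5 samples, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, each batch or day alone, batch left out of the model, tests for changes above 2-fold or 1.5-fold, a prior count of 0.5, Spearman correlations, means in place of medians, mitochondrially encoded genes left out, each sample left out in turn and, added after the data were seen, 6 structural RNA genes left out. GC content, for 16631 of the 19410 tested genes (85.7%), was taken from reference transcripts matched by symbol.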

Results

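Kidney organoids are cultures grown from pluripotent stem cells that pass through mesoderm and form several kidney cell types. RNA was sequenced from 10 samples of such cultures, all made from the human induced pluripotent stem cell line CRL1502 clone C32. Of these, 5 were collected at day 7 and 5 at day 18, and they came from 2 differentiation experiments, here batch 4 and batch 5. Day 7 had 3 samples of batch 4 and 2 of batch 5, and day 18 had 2 of batch 4 and 3 of batch 5. Counts per sample ran from 21.3 to 30.2 M. The labels do not say whether samples of 1 batch were separate cultures, so every p-value measures the spread between these samples, within only 2 differentiation experiments.

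The samples separated first by day and then by batch. The first principal component carried 87.3% of the variance and split day 7 from day 18. The second (4.39%) split the batches at day 7, with group means of -25.5 ± 13.8 (SD, n = 3) in batch 4 and 41.9 ± 11.8 (n = 2) in batch 5, and the third (3.25%) split them at day 18. Median shares of variance over genes were 69.3% between the days, 3.95% between the batches, 3.16% in their interaction and 8.63% within the groups. Each median was taken separately, so the 4 are not the split of any 1 gene. Mean shares were 59.9, 11.2, 9.07 and 16.7% in the same order. Pearson correlations between samples were 0.992 to 0.995 within a batch and day, 0.977 to 0.989 between batches at day 7, 0.985 to 0.987 between batches at day 18, and 0.847 to 0.881 between days.

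**Figure D1:**
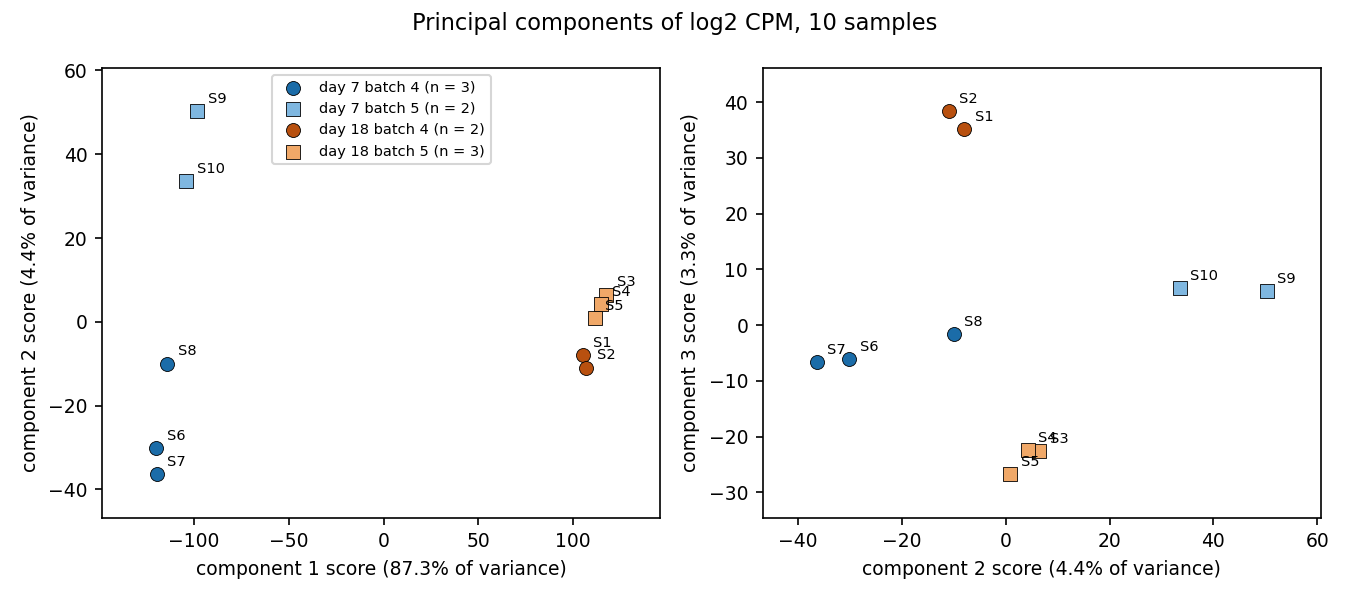
Scores of the 10 samples (points, S1 to S10) on principal components of log2 CPM, components 1 and 2 at left and 2 and 3 at right, with shape for batch and colour for day and batch. Component 1 (87.3% of the variance) separates the days, and S8 (-10.0) lies nearest to the batch 5 samples S9 (50.3) and S10 (33.6) among the day 7 samples of batch 4 on component 2.

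Between day 7 and day 18, most podocyte and nephron tubule genes rose. NPHS1, which encodes nephrin of the podocyte slit diaphragm, rose from 0.617 ± 0.275 to 1001 ± 103 CPM (mean ± SD, n = 5 at each day), 1659 times its day 7 CPM (95% counting interval 1323 to 2109). Of 26 measured podocyte genes 24 rose and 1, the cell cycle inhibitor gene CDKN1C (log2 change -0.21, SE 0.05), fell (median log2 change 5.42, camera adjusted p = 2.67e-09, adjusted p = 0.121 with an estimated correlation). Of 23 proximal tubule genes 21 rose and 1 fell (median 5.50, camera adjusted p = 3.14e-07, adjusted p = 0.171 with an estimated correlation). HNF4A, a transcription factor of this segment, stood at 0.0547 ± 0.0575 and 67.0 ± 13.8 CPM, 1208 times (95% counting interval 586 to 3005, with 7 reads at day 7 and none of them in batch 5). Of 19 genes of the loop of Henle and distal tubule 18 rose and none fell (median 4.88, camera adjusted p = 3.25e-06, adjusted p = 0.121 with an estimated correlation). Among them KCNJ1, a potassium channel gene of the thick ascending limb, had 446 times its day 7 CPM (95% counting interval 152 to 2165). Of 16 genes of the ureteric epithelium and collecting duct 11 rose and 3 fell (median 2.24, camera adjusted p = 0.0335, adjusted p = 0.274 with an estimated correlation). GATA3 had 78.6 times its day 7 CPM (95% counting interval 53.9 to 120) and the water channel gene AQP3 41.4 times (35.3 to 48.9).

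Endothelial, epithelial and stromal genes rose over the same days. CDH5, the cadherin of endothelial junctions, rose from 0.142 ± 0.0816 to 257 ± 44.9 CPM (n = 5 at each day, 1916 times, 95% counting interval 1196 to 3289), and 18 of 20 endothelial genes rose while 1 fell (median 4.45, camera adjusted p = 1.25e-06, adjusted p = 0.201 with an estimated correlation). Genes of epithelial junctions rose in 21 of 24 cases and fell in 1 (median 2.68, camera adjusted p = 1.99e-06, adjusted p = 0.201 with an estimated correlation). Among them was the claudin gene CLDN1 (88.8 times, 95% counting interval 76.2 to 104). In the renal stroma list 15 of 21 genes rose and 3 fell (median 1.01, camera adjusted p = 0.00499, adjusted p = 0.274 with an estimated correlation). TCF21, which is also in the podocyte list, was at 1.04 ± 0.696 and 105 ± 3.36 CPM (99.1 times, 95% counting interval 83.5 to 119). Basement membrane genes rose in 14 of 21 cases and fell in 2 (median 1.30, camera adjusted p = 0.00149, adjusted p = 0.121 with an estimated correlation). NPNT, which encodes the integrin ligand nephronectin, had 338 times its day 7 CPM (95% counting interval 285 to 403). Of the 22 fibrillar collagen and matrix genes, 14 rose and 6 fell, and the list did not move as a whole (camera adjusted p = 0.172).

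Genes of early kidney formation went both ways. The intermediate mesoderm list had 9 genes up and 2 down of 12 (median 3.26, camera adjusted p = 0.0139, adjusted p = 0.274 with an estimated correlation): LHX1 rose from 0.506 ± 0.255 to 31.2 ± 12.5 CPM (n = 5 at each day), while SALL1 (log2 change -3.88, SE 0.07) and OSR1 (-2.21, SE 0.18), transcription factor genes of kidney progenitors, fell. Genes of the renal vesicle and S-shaped body rose in 13 of 16 cases and fell in 2, FGF8 and DLL1 (median 1.83, camera adjusted p = 0.00254, adjusted p = 0.274 with an estimated correlation). The Notch pathway list had 12 up and 3 down of 18 (median 2.15, camera adjusted p = 0.0223, adjusted p = 0.277 with an estimated correlation). The ligand gene DLL4 had 83.8 times its day 7 CPM (95% counting interval 73.2 to 96.4), and the ligand gene DLL3 was at a log2 change of -5.39 (SE 0.27). The 19 nephron progenitor genes split into 9 up and 8 down (camera adjusted p = 0.975): DAPL1 (137 times, 95% counting interval 66.1 to 341) and LYPD1 (96.3 times, 73.1 to 130) rose, and CITED1 (log2 change -4.90, SE 0.23) and MEOX1 (-5.05, SE 0.25) fell.

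**Figure D2:**
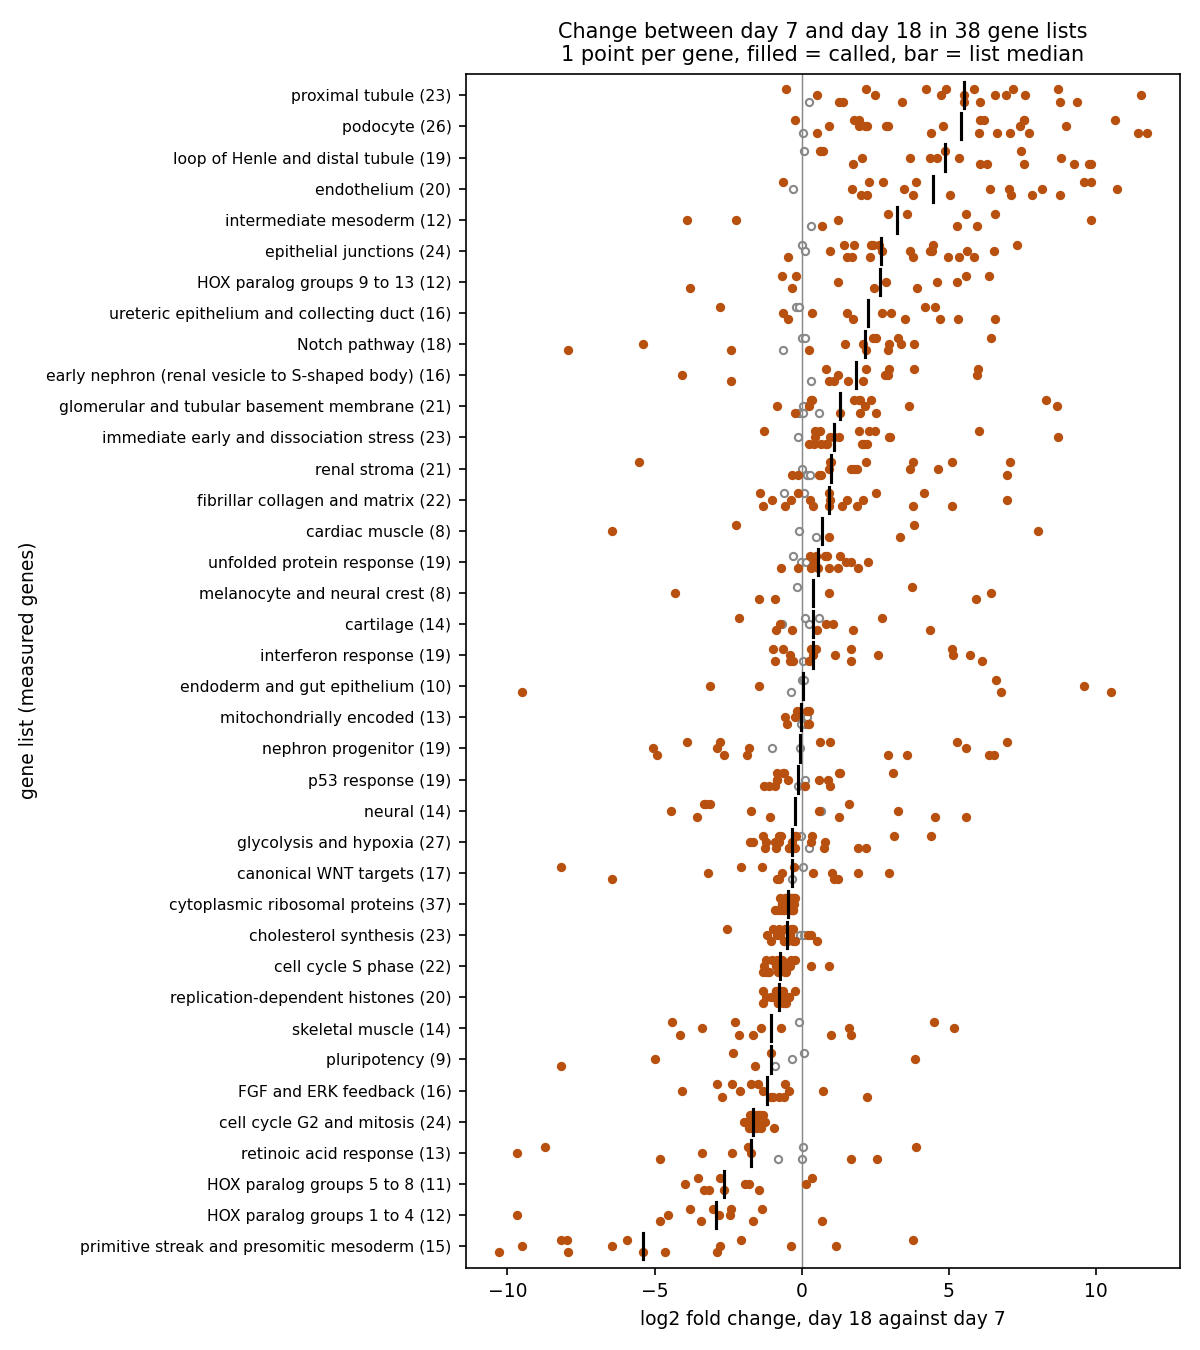
Log2 fold change between day 18 and day 7 (horizontal axis, n = 5 samples at each day) for each measured gene (points, filled where called) of 38 gene lists ordered by their median (bars). Medians run from -5.39 for presomitic mesoderm to 5.50 for the proximal tubule.

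Mesoderm patterning genes fell between the days. CDX2, a caudal patterning gene, fell from 155 ± 70.1 to 0.172 ± 0.138 CPM (n = 5 at each day, log2 change -9.51, SE 0.35), and 13 of 15 genes of the primitive streak and presomitic mesoderm fell while 2 rose (median -5.39, camera adjusted p = 0.000263, adjusted p = 0.274 with an estimated correlation). MSGN1, a presomitic transcription factor gene, had at day 7 1916 times its day 18 CPM (95% counting interval 344 to 75720). HOX genes of paralog groups 1 to 4, which pattern anterior regions, fell in 11 of 12 cases (median -2.91, camera adjusted p = 3.17e-05, adjusted p = 0.274 with an estimated correlation), from HOXB1 (1088 times its day 18 CPM at day 7, 95% counting interval 425 to 3994) to the single gene that rose, HOXD1 (log2 change 0.68, SE 0.08). Paralog groups 5 to 8 fell in 9 of 11 cases and rose in 2 (median -2.64, camera adjusted p = 0.000765, adjusted p = 0.274 with an estimated correlation). In paralog groups 9 to 13, 8 of 12 genes rose and 4 fell (camera adjusted p = 0.240). HOXD11 and HOXA11, genes of the metanephric mesenchyme, had 51.4 and 33.8 times their day 7 CPM (95% counting intervals 27.7 to 108 and 20.3 to 60.8), and HOXB9 was at a log2 change of -3.78 (SE 0.05). LIN28A, an RNA-binding gene of stem cells, fell from 504 ± 19.5 to 1.76 ± 0.515 CPM, and the 9 measured pluripotency genes had 5 down and 1 up (median -1.05, camera adjusted p = 0.0335, adjusted p = 0.274 with an estimated correlation).

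Proliferation and biosynthesis genes fell too. All 24 genes of the G2 phase and mitosis fell (median -1.65, camera adjusted p = 9.36e-09, adjusted p = 0.341 with an estimated correlation). Among them the mitotic kinase gene PLK1 stood at 95.1 ± 20.3 and 23.1 ± 2.08 CPM (n = 5 at each day). S phase genes fell in 20 of 22 cases, with SLBP and CCNE2 rising (median -0.74, camera adjusted p = 4.92e-05, adjusted p = 0.373 with an estimated correlation). All 20 replication-dependent histone genes fell (median -0.77, camera adjusted p = 1.99e-06, adjusted p = 0.343 with an estimated correlation). All 37 cytoplasmic ribosomal protein genes fell by small amounts (median -0.45, camera adjusted p = 1.81e-09, adjusted p = 0.274 with an estimated correlation). FGF and ERK feedback genes fell in 14 of 16 cases (median -1.19, camera adjusted p = 0.000534, adjusted p = 0.274 with an estimated correlation). SPRY2, which restrains receptor signalling, was at -2.89 (SE 0.07), while EGR1 and DUSP5 rose. Cholesterol synthesis genes fell in 18 of 23 cases and rose in 3 (median -0.51, camera adjusted p = 0.000391, adjusted p = 0.274 with an estimated correlation). Of 27 glycolysis and hypoxia genes 17 fell and 8 rose (17 and 9 adjusted over the list alone), and the list did not move (camera adjusted p = 0.126). VEGFA, the endothelial growth factor gene, rose by 4.41 (SE 0.12) against a fall of LDHA (-1.75, SE 0.12).

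Among all genes, the largest fitted rises from at least 10 CPM on average with the same direction in both batches included MYCT1, CDH9 and MMP1, which had 3 or fewer reads in the day 7 samples together, and HNF4A, ESM1 and CLIC5. HNF4A had no read in batch 5 at day 7, and its pooled CPM rose 1208 times (95% counting interval 586 to 3005). MYCT1 had 3082 times its day 7 CPM (95% counting interval 1054 to 14950). CDH9, a cadherin gene, had 4289 times (769 to 169400) and MMP1, a collagenase gene, 5378 times (965 to 212500). ESM1, an endothelial proteoglycan gene, and CLIC5, a podocyte chloride channel gene, rose to 134 ± 12.7 and 335 ± 25.1 CPM (n = 5), 3377 times (95% counting interval 1447 to 10400) and 3002 times (1789 to 5492) their day 7 CPM. The largest fitted falls were in URAD (2582 times its day 18 CPM at day 7, 95% counting interval 883 to 12520), HOXB1, CDX2, FGF18 (log2 change -9.34, SE 0.39), LINC00617 (537 times, 246 to 1463), HTR3A (405 times, 213 to 887), LIN28A (log2 change -8.18, SE 0.11) and CDX4 (-7.98, SE 0.35).

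In total, 15395 of 19410 genes (79.3%) changed between the days (edgeR, adjusted p below 0.05, n = 5 at each day), 7768 up and 7627 down. Of these, 6351 changed over 2-fold, 3491 up and 2860 down, and 1358 rose and 348 fell over 8-fold. In the fit of all 10 samples, 14326 genes were called within batch 4 and 13380 within batch 5. Of the 11531 called in both, 11280 (97.8%) had the same direction. With the samples of each batch fitted alone, 13977 genes were called in batch 4 and 13004 in batch 5. Of 38 gene lists 23 moved, 13 up and 10 down, and no list kept its call with an estimated correlation. In 4 of 100 splits of the samples into 5 and 5, the split by day among them, as many lists moved. The other splits mix the days and can carry part of their difference, so they give no chance value for this number. With a test for changes above 2-fold, 4810 genes were called. Unless given, the counts of called genes in these lists were the same adjusted over the list alone, and the list medians the same with low counts at their bound.

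**Figure D3:**
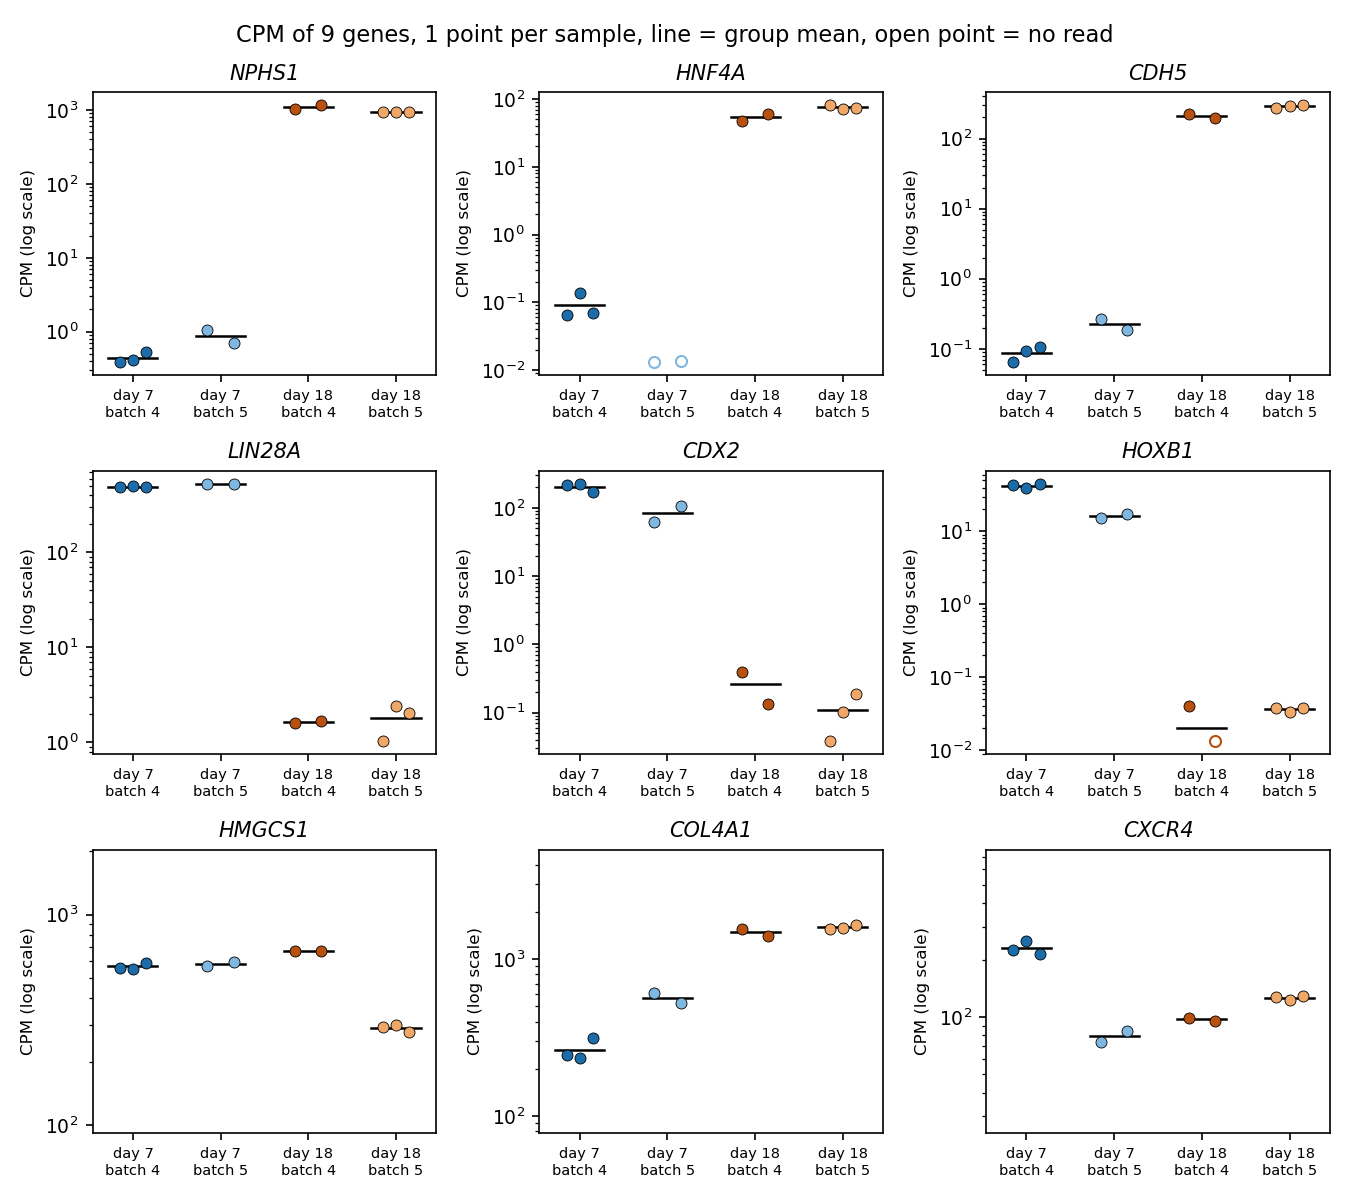
CPM on a log scale (vertical axis) of 9 genes in each of the 4 groups of day and batch, 1 point per sample, with the group mean as a line; open points have no read and stand at an arbitrary low height. NPHS1, HNF4A and CDH5 rise and LIN28A, CDX2 and HOXB1 fall between the days in both batches, HMGCS1 is lower in batch 5 at day 18, COL4A1 is higher in batch 5 at day 7, and CXCR4 differs in opposite directions at the 2 days.

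At day 7, most matrix genes and 8 of 20 endothelial genes were higher in batch 5 than in batch 4. Most presomitic genes and HOX genes of paralog groups 1 to 8 were lower. HOXB1 stood at 42.6 ± 3.04 CPM in batch 4 (n = 3) and 16.5 ± 1.53 CPM in batch 5 (n = 2), a log2 difference of -1.37 (SE 0.09, edgeR adjusted p = 2.83e-08). All 12 measured genes of HOX paralog groups 1 to 4 were lower in batch 5 (median -0.74, camera adjusted p = 8.60e-07, adjusted p = 0.395 with an estimated correlation). Of 11 genes in groups 5 to 8, 8 were lower and none higher (9 lower and 1 higher adjusted over the list alone, median -0.36, camera adjusted p = 0.00294, adjusted p = 0.421 with an estimated correlation). Groups 9 to 13 did not move, with 2 of 12 genes higher and none lower (median 0.05, or 0.11 with low counts at their bound, camera adjusted p = 0.524). Presomitic genes were lower in 8 of 15 cases and higher in 1, CDX1 (median -0.99, camera adjusted p = 0.0162, adjusted p = 0.526 with an estimated correlation). CDX4 was at -1.65 (SE 0.23). Retinoic acid response genes, several of them HOX genes, were lower in 8 of 13 cases and higher in 1 (median -0.55, camera adjusted p = 0.00190, adjusted p = 0.395 with an estimated correlation). CYP26A1, which encodes a retinoic acid hydroxylase, was at -1.43 (SE 0.34).

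Matrix genes were higher in batch 5 at day 7. Fibrillar collagen and matrix genes were higher in batch 5 in 16 of 22 cases and lower in 1 (17 and 1 adjusted over the list alone, median 0.87, camera adjusted p = 1.08e-06, adjusted p = 0.395 with an estimated correlation). Basement membrane genes were higher in 14 of 21 cases and lower in 2 (median 0.44, or 0.41 with low counts at their bound, camera adjusted p = 2.91e-05, adjusted p = 0.0833 with an estimated correlation): NID2, which encodes nidogen 2, stood at 99.2 ± 17.7 and 357 ± 58.8 CPM (n = 3 and 2, log2 difference 1.84, SE 0.15), and the type IV collagen gene COL4A1 at 264 ± 42.6 and 567 ± 61.1 CPM (1.10, SE 0.12). Of 20 endothelial genes 8 were higher and 1 lower (10 and 1 adjusted over the list alone, median 1.17, or 1.22 with low counts at their bound, camera adjusted p = 0.00286, adjusted p = 0.421 with an estimated correlation). Several endothelial genes had few reads: CDH5 had 17, CLDN5 36 and SOX17 5 over the day 7 samples. SOX18 had 13 in batch 5 and 6 in batch 4. KDR, a VEGF receptor gene, was at 1.78 (SE 0.22). Stromal genes were higher in 9 of 21 cases and lower in 2 (median 0.63, camera adjusted p = 0.0162, adjusted p = 0.493 with an estimated correlation). TBX18 was at 3.86 (SE 0.32). Podocyte genes were higher in 9 of 26 cases and lower in 2 (9 and 3 adjusted over the list alone, median 0.42, camera adjusted p = 0.0131, adjusted p = 0.421 with an estimated correlation). WT1 was at -0.75 (SE 0.08). Of 24 epithelial junction genes 6 were lower and none higher, and the list did not move (median -0.03, or 0.07 with low counts at their bound, camera adjusted p = 0.628).

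Mitochondrial and glycolytic genes were lower in batch 5 at day 7. All 13 mitochondrially encoded genes were lower in batch 5 (median -0.60, camera adjusted p = 7.59e-08, adjusted p = 0.395 with an estimated correlation). Such genes held 0.659 ± 0.0389% of the counts in batch 4 (n = 3) and 0.423 ± 0.0357% in batch 5 (n = 2). Glycolysis and hypoxia genes were lower in 12 of 27 cases and higher in 3 (median -0.20, camera adjusted p = 0.0105, adjusted p = 0.526 with an estimated correlation). PDK1, a kinase gene that limits pyruvate oxidation, was at -0.83 (SE 0.12). Ribosomal protein genes were higher in 10 of 37 cases (median 0.07, camera adjusted p = 0.00773, adjusted p = 0.757 with an estimated correlation). Genes of the G2 phase and mitosis were lower in 4 of 24, none adjusted over the list alone (median -0.24, camera adjusted p = 0.00294, adjusted p = 0.757 with an estimated correlation). The interferon response list had 3 of 19 genes higher (median 0.34, or 0.28 with low counts at their bound, camera adjusted p = 0.0106, adjusted p = 0.395 with an estimated correlation). The restriction factor gene BST2 was at 0.50 (SE 0.07). Of 23 cholesterol synthesis genes 6 were lower and 1 higher (6 and 3 adjusted over the list alone), with INSIG1 at -0.44 (SE 0.07), and the list did not move (camera adjusted p = 0.453).

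Among genes of at least 1 CPM at day 7, the largest differences toward batch 5 were in SIM1, a nephron transcription factor gene (0.124 ± 0.111 and 19.4 ± 14.5 CPM, n = 3 and 2, log2 difference 7.24, SE 0.93), the mesodermal homeobox gene MEOX2 (6.38, SE 0.86), TBX2 (4.93, SE 0.66), the angiotensin receptor gene AGTR2 (4.66, SE 0.75), TNC (4.40, SE 0.76), FMOD (4.26, SE 0.54), LURAP1L (4.20, SE 0.41) and OR51E1 (4.05, SE 0.33). The largest toward batch 4 were in CNTNAP4 (-4.78, SE 1.06), C2CD4A (-4.37, SE 0.86), PITX1 (-4.30, SE 0.69), NEUROG3 (-3.80, SE 0.75), C2CD4B (-3.69, SE 0.67), the Notch ligand-like gene DLK1 (-3.62, SE 0.74), BARX1 (-3.31, SE 0.51) and KCNF1 (9.21 times its batch 5 CPM in batch 4, 95% counting interval 5.48 to 16.7). Without S9, the calls for CNTNAP4 (-3.95), C2CD4A (-3.48), PITX1 (-3.63), NEUROG3 (-3.64) and DLK1 (-2.87) were lost, and so were those for CNTNAP4 and NEUROG3 without S6 or S10. With limma-voom the calls for CNTNAP4, C2CD4A and PITX1 were lost as well. In total 5036 of 19410 genes differed between the batches at day 7 (edgeR, n = 3 and 2), 2921 higher and 2115 lower in batch 5, 844 of them over 2-fold (475 and 369), and 14 lists moved, 7 up and 7 down. Scaled by library totals alone, the split turned to 2249 higher and 3036 lower, and without S9 2847 genes were called. With a test for differences above 1.5-fold, 316 were.

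At day 18, cholesterol synthesis genes were lower in batch 5 than in batch 4, the list with the smallest p. HMGCS1, which encodes an early enzyme of cholesterol synthesis, stood at 674 ± 0.574 CPM in batch 4 (n = 2) and 290 ± 12.1 CPM in batch 5 (n = 3), a log2 difference of -1.22 (SE 0.05, edgeR adjusted p = 7.09e-10). The 2 batch 4 values of HMGCS1, 673.7 (S1) and 674.6 CPM (S2), lie closer than counting error alone would usually give. Their SD is therefore not a measure of precision. INSIG1, a sterol-regulated gene, stood at 336 ± 4.43 and 128 ± 5.01 CPM (-1.39, SE 0.07). Of 23 cholesterol synthesis genes 22 were lower in batch 5 and none higher (median -0.67, camera adjusted p = 1.32e-22, adjusted p = 0.134 with an estimated correlation). Glycolysis and hypoxia genes were lower in 18 of 27 cases and higher in 1 (21 and 3 adjusted over the list alone, median -0.44, camera adjusted p = 1.07e-09, adjusted p = 0.306 with an estimated correlation). The glucose transporter gene SLC2A1 was at 158 ± 18.9 and 47.8 ± 0.946 CPM (-1.73, SE 0.08) and HK2 at -0.98 (SE 0.09). Of 13 mitochondrially encoded genes 10 were lower (11 adjusted over the list alone, median -0.44, camera adjusted p = 4.86e-06, adjusted p = 0.356 with an estimated correlation), at 0.725 ± 0.122% of the counts in batch 4 and 0.505 ± 0.0219% in batch 5 (n = 2 and 3).

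Tubule genes were higher and genes of the early nephron lower in batch 5 at day 18. Proximal tubule genes were higher in batch 5 in 16 of 23 cases and lower in none (17 adjusted over the list alone, median 0.51, camera adjusted p = 2.19e-06, adjusted p = 0.306 with an estimated correlation). ANPEP, a brush border peptidase gene, stood at 8.03 ± 0.418 and 30.8 ± 4.96 CPM (n = 2 and 3, log2 difference 1.94, SE 0.16), and SLC22A6, an organic anion transporter gene, at 2.21 (SE 0.25). Genes of the loop of Henle and distal tubule were higher in 9 of 19 cases and lower in 2 (median 0.26, camera adjusted p = 0.0434, adjusted p = 0.356 with an estimated correlation). The sodium cotransporter gene SLC12A1 was at 38.1 ± 2.29 and 115 ± 13.9 CPM (1.59, SE 0.11). Genes of the renal vesicle and S-shaped body were lower in 9 of 16 cases and higher in 3 (11 and 3 adjusted over the list alone, median -0.52, camera adjusted p = 0.0276, adjusted p = 0.490 with an estimated correlation): LHX1 was at -1.01 (SE 0.11) and FGF8 had 22.8 times its batch 5 CPM in batch 4 (95% counting interval 10.03 to 64.1). Intermediate mesoderm genes were lower in 8 of 12 cases and higher in 1, GATA3 (10 and 1 adjusted over the list alone, median -0.70, camera adjusted p = 0.00866, adjusted p = 0.356 with an estimated correlation). Notch pathway genes were lower in 7 of 18 cases and higher in 1, JAG2 (median -0.33, or -0.36 with low counts at their bound, camera adjusted p = 0.00722, adjusted p = 0.356 with an estimated correlation). The target gene HEYL was at -0.79 (SE 0.07). HOX genes of groups 9 to 13 were lower in 7 of 12 cases (10 adjusted over the list alone, median -0.69, camera adjusted p = 0.00233, adjusted p = 0.384 with an estimated correlation), HOXD11 among them at -1.42 (SE 0.18), while none of groups 1 to 8 was called.

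Stromal and cartilage genes were higher in batch 5 at day 18, and histone, S phase and ribosomal protein genes lower. In the renal stroma list 10 of 21 genes were higher and none lower (median 0.45, camera adjusted p = 0.000196, adjusted p = 0.348 with an estimated correlation). The matrix gene POSTN was at 107 ± 24.5 and 330 ± 4.35 CPM (n = 2 and 3, log2 difference 1.62, SE 0.18). Fibrillar collagen and matrix genes were higher in 11 of 22 cases (13 adjusted over the list alone, median 0.51, camera adjusted p = 6.52e-05, adjusted p = 0.356 with an estimated correlation). Of 14 cartilage genes 8 were higher and 1, HAPLN1, lower (9 and 1 adjusted over the list alone, median 0.75, camera adjusted p = 7.03e-05, adjusted p = 0.348 with an estimated correlation). COL9A3, a collagen gene of cartilage, was at 3.48 (SE 0.14). Retinoic acid response genes were higher in 3 of 13 cases (5 adjusted over the list alone, median 0.30, or 0.29 with low counts at their bound, camera adjusted p = 0.0442, adjusted p = 0.448 with an estimated correlation). Replication-dependent histone genes were lower in 16 of 20 cases (18 adjusted over the list alone, median -0.32, camera adjusted p = 3.64e-08, adjusted p = 0.384 with an estimated correlation). S phase genes were lower in 10 of 22 cases (16 adjusted over the list alone, median -0.25, camera adjusted p = 2.75e-05, adjusted p = 0.485 with an estimated correlation). Genes of the G2 phase and mitosis were lower in 2 of 24, none adjusted over the list alone (median -0.21, camera adjusted p = 0.00528, adjusted p = 0.782 with an estimated correlation). Ribosomal protein genes were lower in 24 of 37 cases (28 adjusted over the list alone, median -0.16, camera adjusted p = 3.64e-08, adjusted p = 0.384 with an estimated correlation). Genes of the unfolded protein response were lower in 9 of 19 (median -0.16, camera adjusted p = 0.000422, adjusted p = 0.312 with an estimated correlation). ASNS, which encodes asparagine synthetase, was at -0.78 (SE 0.06).

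Among genes of at least 1 CPM at day 18, STAB2, a scavenger receptor gene, had 162 times its batch 4 CPM in batch 5 (95% counting interval 44.6 to 1339; 2 and 561 reads) and NPY5R 60.3 times (16.5 to 501). NCAM2 (15.3 times, 11.3 to 21.03), CLEC3B (12.9 times, 5.77 to 35.7), COL9A3, the neuropeptide Y receptor gene NPY1R (log2 difference 3.48, SE 0.15), LECT1 (3.43, SE 0.44) and CPB1 (9.45 times, 6.36 to 14.6) followed. The largest differences toward batch 4 were in HAND2 (log2 difference -3.11, SE 0.34), ISL1 (-3.03, SE 0.36), PLA2G3 (7.56 times its batch 5 CPM in batch 4, 95% counting interval 4.86 to 12.2), LAMP5 (log2 difference -2.65, SE 0.20), IRX4 (-2.51, SE 0.24), PCSK1 (-2.45, SE 0.14), CALY (-2.29, SE 0.23) and SHOX2 (-2.29, SE 0.28). In total 4323 of 19410 genes differed between the batches at day 18 (edgeR, n = 2 and 3), 2071 higher and 2252 lower in batch 5, 728 of them over 2-fold (478 and 250), and 18 lists moved, 6 up and 12 down. The share higher in batch 5 ran from 47.2 to 65.2% over the alternatives, with 2424 higher and 1945 lower scaled by library totals alone. Without S1 2508 genes were called and without S2 2105, each of which leaves 1 sample in batch 4, and with a test for differences above 1.5-fold 471 were.

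**Figure D4:**
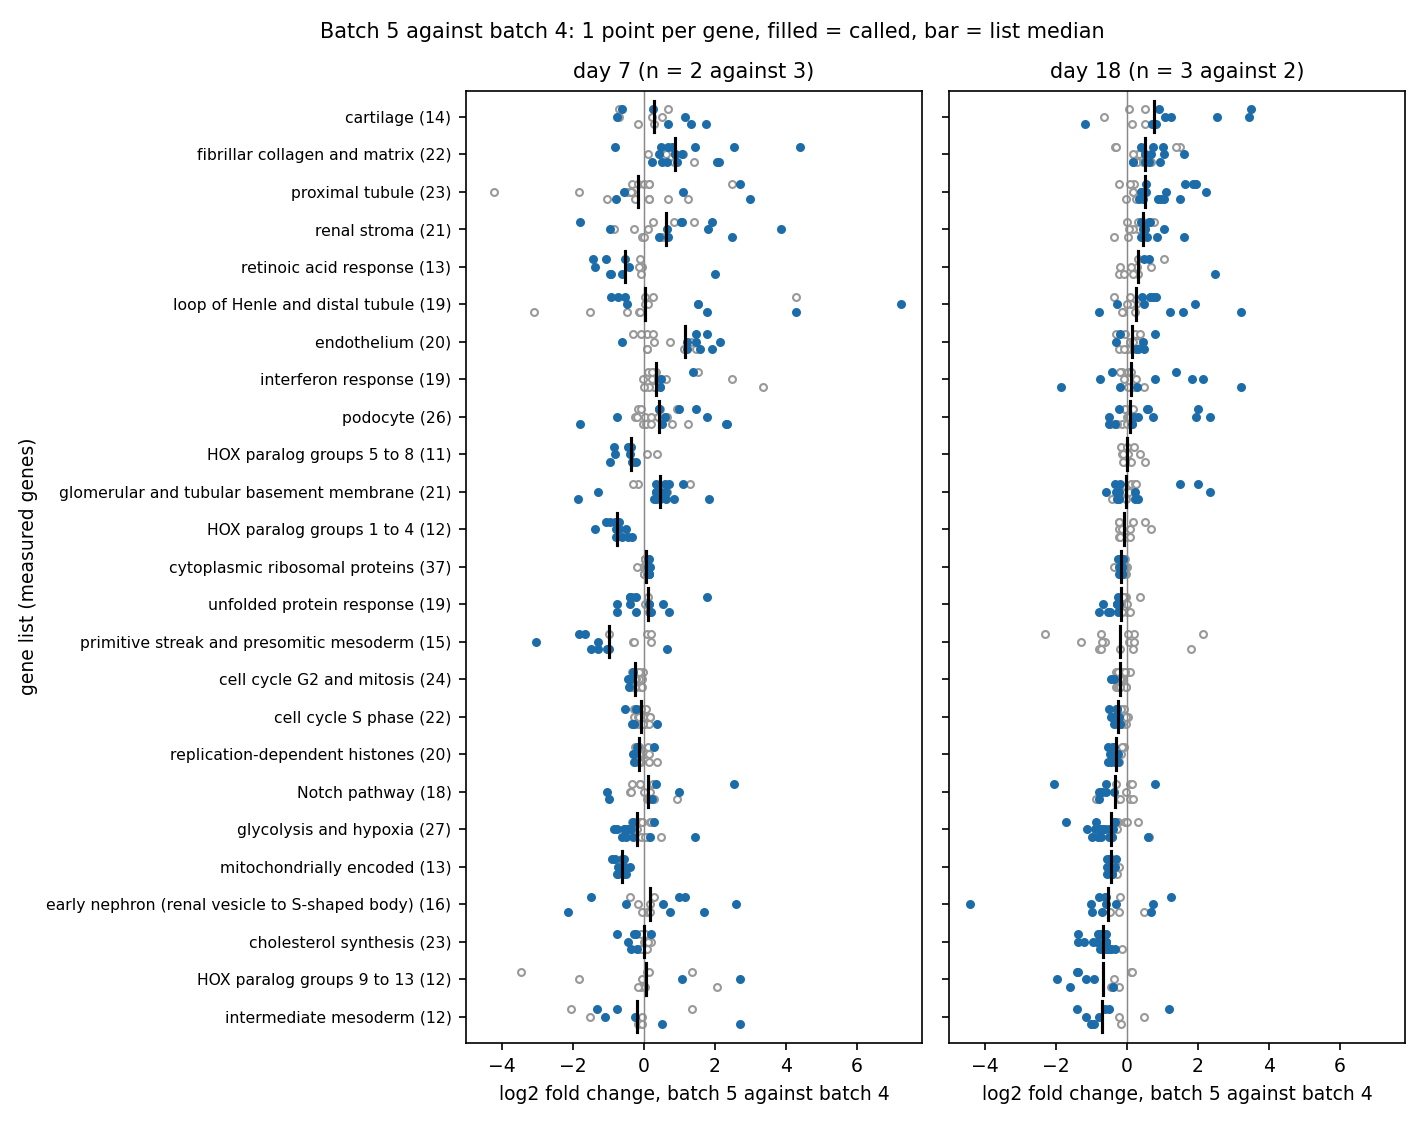
Log2 fold change between batch 5 and batch 4 (horizontal axis) at day 7 (left, n = 2 against 3) and day 18 (right, n = 3 against 2) for each measured gene (points, filled where called) of the lists that moved at either day, with the list median as a bar. HOX groups 1 to 4 lie below 0 at day 7 (median -0.74) and cholesterol synthesis genes at day 18 (median -0.67).

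The batch difference depended on the day for 3536 genes (edgeR interaction, n = 3, 2, 2 and 3), 1322 with a higher value of batch 5 against batch 4 at day 18 than at day 7 and 2214 with a lower one. CXCR4, a chemokine receptor gene, was lower in batch 5 at day 7 (232 and 79.1 CPM) and higher at day 18 (97.3 and 126 CPM), an interaction of 1.93 on the log2 scale. ADAMTS19 (2.82), DAAM2 (1.67), GFOD1 (1.56) and the neprilysin gene MME (1.04) had the same direction, and FBLN2 (-2.09), RMST (-2.44), HMGCS1 (-1.26) and the fatty acid desaturase genes SCD (-1.36) and FADS2 (-1.11) the opposite one. Among the called genes, 2042 changed between the days in the same direction in both batches and 251 in opposite directions. Scaled by library totals alone, the split turned to 1957 higher and 1467 lower. Without S1 2236 genes were called and without S2 2049.

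By list, cholesterol synthesis had the smallest p for the interaction: 21 of 23 genes had a lower batch difference at day 18 and none a higher one (camera adjusted p = 5.22e-14, adjusted p = 0.347 with an estimated correlation). Ribosomal protein genes followed with 25 of 37 (31 adjusted over the list alone, camera adjusted p = 1.21e-08, adjusted p = 0.486 with an estimated correlation). Glycolysis and hypoxia had 8 of 27 (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00324, adjusted p = 0.486 with an estimated correlation). Histones had 7 of 20 (9 adjusted over the list alone, camera adjusted p = 0.00270, adjusted p = 0.662 with an estimated correlation). Basement membrane genes had 12 of 21 lower and 2 higher (13 and 4 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.347 with an estimated correlation). NID2 was at -2.10 (SE 0.21). Genes of the renal vesicle and S-shaped body had 6 of 16 lower and 1 higher (10 and 2 adjusted over the list alone, camera adjusted p = 0.00734, adjusted p = 0.486 with an estimated correlation). The Notch pathway had 6 of 18 lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.0171, adjusted p = 0.486 with an estimated correlation). HOX genes of groups 9 to 13 had 4 of 12 lower (camera adjusted p = 0.00734, adjusted p = 0.487 with an estimated correlation). Higher at day 18 were 6 of 12 HOX genes of groups 1 to 4 (camera adjusted p = 7.51e-05, adjusted p = 0.486 with an estimated correlation), HOXA3 among them at 1.12 (SE 0.14). The same held for 4 of 11 genes of groups 5 to 8 (6 adjusted over the list alone, camera adjusted p = 0.00734, adjusted p = 0.486 with an estimated correlation).

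Some retinoic acid response, proximal tubule and cartilage genes also had higher batch differences at day 18. Of 13 retinoic acid response genes 6 did (7 adjusted over the list alone, camera adjusted p = 0.000199, adjusted p = 0.431 with an estimated correlation). STRA6, a retinol transporter gene, was at 1.17 (SE 0.14). Of 23 proximal tubule genes 4 had a higher and 1, DPP4, a lower difference (camera adjusted p = 0.00114, adjusted p = 0.486 with an estimated correlation). The endocytic receptor gene LRP2 was at 1.68 (SE 0.28). Of 14 cartilage genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0422, adjusted p = 0.568 with an estimated correlation), from COL9A2 at 1.85 (SE 0.22) to HAPLN1 at -2.91 (SE 0.16).

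Across the 19410 genes, the log2 change between the days in batch 4 and in batch 5 correlated at r = 0.918, against 0.979 in data simulated with equal batches. The batch differences at the 2 days correlated at r = 0.0839 (simulated range -0.0304 to 0.0299), and at 0.0532 without S9. Among called genes, 586 were higher in batch 5 at both days and 355 lower at both, where independent calls would share 312 and 245. In opposite directions, 317 were higher at day 7 and lower at day 18 and 161 the reverse, where 339 and 226 would be shared. The day 7 batch difference correlated with the difference between days at r = 0.193 (simulated mean -0.0256) and the day 18 batch difference at r = 0.0926 (simulated mean -0.0217). The simulations carry the libraries shared by both comparisons but draw each gene independently. The day 18 value was 0.0348 without S1 and 0.0357 by Spearman. The day 7 value was 0.331 against the change between days in batch 4 alone and 0.0423 against that in batch 5 alone, and the day 18 value -0.0361 and 0.222, where each of these shares the libraries of 1 batch with the same or the opposite sign.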

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

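Of the tests in this part, those of batch 5 being uniformly ahead, of fewer cycling cells and of the spread along the batch axis were chosen only after the result was seen. The interaction results were singled out because the batch difference was not the same at the 2 days by the test of that difference, and the last 2 patterns weighed were not singled out by that test. Groups of 2 and 3 samples are too small to test for a single sample apart from the others, and no data beside the counts were left to examine.

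The interaction of batch and day called 3536 genes. The log2 interactions of the genes with the smallest adjusted p were 1.93 for CXCR4, 1.67 for DAAM2, 2.82 for ADAMTS19, 1.04 for MME and 1.56 for GFOD1, and -2.09 for FBLN2, -1.26 for HMGCS1, -1.11 for FADS2, -1.36 for SCD and -2.44 for RMST. List medians of the interaction were 0.64 for the proximal tubule, 0.28 for cartilage, 0.72 for the retinoic acid response, 0.64 for HOX groups 1 to 4 and 0.33 for HOX groups 5 to 8. They were -0.80 for the early nephron, -0.33 for the Notch pathway, -0.52 for basement membrane, -0.39 for HOX groups 9 to 13, -0.29 for glycolysis and hypoxia, -0.64 for cholesterol synthesis, -0.25 for histones and -0.21 for ribosomal proteins.

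The cholesterol synthesis list was lower in batch 5 at day 18 (adjusted p = 0.134 with an estimated correlation) and did not move at day 7. None of 10000 random lists matched on GC content, length and expression had a median as low (0 of them, lowest -0.19). This argues against GC content and gene length. The median stayed at -0.64 and -0.67 under library-total and RLE scaling, so the choice among these methods did not produce it. TMM factors lay between 0.979 (S10) and 1.024 (S7), so a change of method could move the median little. The comparison does not test scaling beyond that choice. Fewer cycling cells in batch 5 would need mitotic genes as low. Their median was -0.21 (95% interval over resampled list members -0.26 to -0.14), outside the interval of the cholesterol list (-0.81 to -0.60). These intervals are over genes and do not measure the spread between samples or experiments, so they alone cannot exclude fewer cycling cells. A difference in sterol or lipid supply between the 2 experiments is a hypothesis left open and was not tested, since the labels give 1 protocol for all samples. Each batch at day 18 is 1 differentiation experiment, so this cannot be assigned to the cells or to their handling.

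The day 7 batch difference followed the change between days: the covariance across genes was 0.154 with libraries shared by both comparisons, where simulations with equal batches reached at most 0.00134. The correlation was 0.173 after trends on GC content and gene length were taken out (0.180 before, in the genes with a GC value) and 0.196 with all libraries thinned to 21307023 counts. This argues against GC content or gene length bias and different sequencing depth as the whole of the pattern. The simulations drew each gene independently, so they lack variation that many genes of a shared library have in common. Shared libraries therefore cannot be excluded as a cause. The correlation was 0.331 against the change between days in batch 4 alone and 0.0423 against that in batch 5 alone. If batch 5 were uniformly ahead on the course from day 7 to day 18, epithelial junction genes should be higher by 0.17. Their median was -0.051 in log2 CPM (95% interval over resampled list members -0.16 to 0.28, which includes that value), -0.03 by edgeR fold changes and 0.07 with low counts at their bound. At day 7 the list had a median of 1.465 CPM, and 15 of its 24 genes reached 1 CPM, so a shift of 0.17 is hard to see. Over all genes, 1514 were higher in batch 5 and rose between the days and 1129 were lower and fell (1169 and 831 if independent), but 976 were higher and fell and 602 were lower and rose (1148 and 846 if independent), and of the 24 junction genes 6 were lower and none higher. Batch 5 being uniformly ahead cannot be told apart from a difference in some cell types only, since genes need not change steadily and no day between 7 and 18 was measured.

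The samples of 1 batch at day 7 were also compared with each other along the batch difference. S8 minus S6 correlated with the mean of S9 and S10 minus S7, which shares no library with it, at 0.381 over all genes. In genes with a GC value it was 0.423, and 0.431 after trends on GC content and gene length were taken out, which argues against GC content or gene length bias. Other correlations without a shared library, over all genes, were 0.386 for S8 minus S7, 0.129 for S9 minus S10 and 0.0371 for S6 minus S7. S6 and S7 were closer to each other (chi-square per gene 2.70) than to S8 (9.67 and 10.3). What S6 and S7 have in common enters both terms of the S8 correlations with the same sign. Those can therefore be positive without S8 differing along the batch difference. A spread of samples along the between-batch axis was set to need the first 3 above 0.3 and to be excluded by any of them below 0.1. Such a spread cannot be told apart from 1 sample, S8, lying between the batches or from S6 and S7 being alike. For batch 5 it rests on S9 minus S10 alone.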

How the results depend on the processing

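The structural RNA genes were left out only after the data were seen; all other alternatives were planned. Without each replicate in turn, genes called ran from 14896 to 15309 between the days, 2847 to 5623 between the batches at day 7, 2105 to 5050 at day 18 and 2049 to 4207 in the interaction, where a lone sample left in a group is assumed to vary like the others. Lists moved ran from 22 to 23, 13 to 16, 16 to 20 and 12 to 18. RLE scaling called 4939 genes at day 7 and 4238 at day 18, DESeq2 4244 and 3415, limma-voom 4890 and 4386, no filter 4371 and 3789, and without structural RNAs 4984 and 4288 were called. Tests above a fold threshold, which ask more of each gene, called 4810 genes between the days (2-fold), 316 between the batches at day 7 and 471 at day 18 (1.5-fold). Library totals alone turned the split of calls toward lower genes at day 7 (42.6% higher in place of 58.0%) and toward higher genes at day 18 (55.5% in place of 47.9%) and in the interaction (57.2% in place of 37.4%). At day 18 the share higher ran from 47.2% (DESeq2) to 65.2% (1.5-fold) over all alternatives. With an estimated correlation 0 lists moved in each of the 4 contrasts, and with fry 35 moved between the days. The correlation of the batch differences at the 2 days was 0.133 with at least 1 CPM in 5 samples, and 0.0532 to 0.112 without each replicate. That of the day 7 batch difference with the change between days was 0.224 by Spearman, 0.331 and 0.0423 against batch 4 and batch 5 alone, and 0.142 to 0.212 without each replicate. That of the day 18 batch difference was 0.147 with at least 1 CPM, 0.0662 with a prior count of 0.5, 0.0357 by Spearman, -0.0361 and 0.222 against batch 4 and batch 5 alone, the first reversed, and 0.0348 to 0.125 without each replicate. The correlation of the changes in the 2 batches was 0.941 with at least 1 CPM, 0.874 by Spearman and 0.896 to 0.922 without each replicate. Means over genes in place of medians gave variance shares of 59.9% for day, 11.2% for batch, 9.07% for interaction and 16.7% within groups; at least 1 CPM gave 2.77% for interaction and 6.22% within groups. Without each replicate, shares were 61.2 to 73.2%, 3.57 to 4.42%, 2.95 to 3.51% and 6.94 to 8.92%. Where no construction is named, the cause was not tested. Named genes were tested under RLE, library totals alone, DESeq2, limma-voom and without each replicate: none turned direction, and from 4 (RLE) to 90 (without replicate S9) of the named results lost their call. No paired analysis was possible because the groups share no replicate number.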

Other observations

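Of the tests in this part, that of other splits for the genes called between the days was chosen only after the result was seen. Genes of other tissues changed between day 7 and day 18 without a common direction. Of 14 neural genes 6 rose and 7 fell (camera adjusted p = 0.626): the retinoid binding protein gene CRABP1 had 67.7 times its day 7 CPM (95% counting interval 51.7 to 90.6) and the neuronal cytoskeleton gene MAP2 rose by 4.53 on the log2 scale (SE 0.14, n = 5 at each day), while FABP7 was at -3.56 (SE 0.15). Of 14 skeletal muscle genes 5 rose and 8 fell, with PAX3, a gene of muscle progenitors, at -4.41 (SE 0.14). Of 14 cartilage genes 6 rose and 4 fell, ACAN to 23.9 times (95% counting interval 19.5 to 29.7) and COL2A1 at a log2 change of -2.12 (SE 0.05). Of 10 endoderm genes 4 rose and 3 fell, and AFP, the alpha-fetoprotein gene, rose from 0.0311 ± 0.0295 to 83.8 ± 53.9 CPM (n = 5 at each day), with 25.4 CPM in batch 4 and 123 CPM in batch 5 at day 18. Of 8 melanocyte and neural crest genes 4 rose and 3 fell, MITF to 62.5 times (95% counting interval 49.4 to 80.2) and PMEL at a log2 change of -4.31 (SE 0.08). Of 8 cardiac genes 4 rose and 2 fell, and of 4 measured blood genes 3 rose, TAL1 to 350 times (95% counting interval 177 to 810), and 1 fell, HBE1 (24.96 times its day 18 CPM at day 7, 18.9 to 33.7).

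Of 23 immediate early and dissociation stress genes 21 rose and 1, NR4A1, fell between the days (21 and 2 adjusted over the list alone, median 1.09, camera adjusted p = 0.000301, adjusted p = 0.274 with an estimated correlation), and of 19 unfolded protein response genes 14 rose and 2 fell (median 0.54, camera adjusted p = 0.00373, adjusted p = 0.274 with an estimated correlation), with TRIB3 at 2.26 (SE 0.07). Of 19 interferon response genes 12 rose and 6 fell (camera adjusted p = 0.192), of 19 p53 response genes 7 rose and 9 fell (8 and 10 adjusted over the list alone), with GADD45A at 3.12 (SE 0.04), and of 17 canonical WNT target genes 6 rose and 9 fell (camera adjusted p = 0.249), with LEF1 at -2.06 (SE 0.07) and DKK1 at 1.91 (SE 0.09). Of 13 retinoic acid response genes 3 rose and 7 fell (camera adjusted p = 0.107). Of 13 mitochondrially encoded genes 4 rose and 4 fell between the days.

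Other splits of the samples were counted as a test of grouping by chance. With day alone in the model, 1 of 100 splits of the 10 samples into 5 and 5 called as many genes as the split by day. That 1 was the split by day itself, with 14256 genes, and the highest other split called 18. Every other split puts samples of both days on each side, so the difference between the days enters the spread within its groups. Few calls were fixed in advance for such splits, and this count cannot test grouping by chance. As many lists as the split by day (23) moved in 4 of 100 splits, itself included, and the other splits moved 5 to 23. Those splits can still carry part of the difference between the days, so they give no chance value. Whether 23 lists exceed chance cannot be told from them. Among the 10 splits of the 5 day 7 samples into 2 and 3, 1, the split by batch, called 3704 genes, and the highest other, S6 and S7 against S8, S9 and S10, called 70; among the 10 splits of the day 18 samples, 1, the split by batch, called 5558 and every other 0. With 10 splits these counts cannot exclude chance.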
